A study of Mus musculus with 13 samples.

How the data were processed

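Gene expression was measured with Clariom S mouse arrays in RNA pooled from 4T1 mammary tumours. The tumours had grown in the mammary fat pad of WT or Nlrx1-/- BALB/c mice after injection of 1 of 3 cell lines. These were parental 4T1, a mouse mammary carcinoma line that grows in BALB/c mice, a transduced line overexpressing NLRX1 (4T1OE), and its transduced control line (4T1OE-CTL). Each of the 6 groups held 2 arrays, and each array was hybridised with a pool, so the spread between arrays was a spread between pools. The number of tumours in a pool was not given in the sources used here.

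The deposited values were log2 expression values, 1 per transcript cluster and array, which the authors had normalized and summarised. The Transcriptome Analysis Console was named per the submitters' processing notes, without a version. The background and normalization method was not given in the sources used here. The values were used as deposited, without further scaling. Array medians ran from 5.89 to 6.25 and the standard deviations of the values within an array from 2.53 to 3.12, so the arrays had not been brought to 1 common distribution. On 3 arrays the highest value was 19.931.

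The table held 28846 features. Control features were removed, 6640 in all, of which 6546 carried the prefix MG-1, 31 the prefix AFFX and 63 the prefix ERCC. The remaining 22206 features were all tested. Of these, 19572 had 1 gene symbol and 2634 had none in the annotation available. Where a gene had more than 1 feature, as 55 genes did, the feature with the highest mean stood for the gene. No genome build was named with the values, and no coordinates were used.

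The array service had recommended leaving out 1 sample, given by the service's own code. It was inferred here to be the Nlrx1-/- parental replicate 1 array, from its place in the order of the tumour arrays. That array also had the lowest median correlation with the others (r = 0.896 across features). It was left out of the fits, so 11 of the 12 tumour arrays were fitted and 1 Nlrx1-/- parental array remained, which was assumed to vary as the other groups did. Of all 66 pairs of tumour arrays none was identical, and the lowest correlation between fitted arrays was 0.948. The column of the manufacturer's control array held no values.

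Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all features tested and an adjusted p threshold of 0.05. An additive model of host genotype and cell line gave the differences averaged over lines or genotypes. A model with 1 mean for each of the 6 groups gave the differences within a line or genotype and their interaction. The comparison of 4T1OE with parental tumours was added after the data had been seen, and the other 9 comparisons had been fixed in advance, as were the gene lists, the rule for naming genes and the first group of alternative settings below. Where every array on 1 side of a comparison lay under its own median of the negative control features for a gene, a bound replaced the fitted difference. The bound ran from the brighter side's mean to the other side's mean of, per array, the higher of that median and the gene's value. No size was given where both sides lay under it or the bound was not above 0. The level of Nlrx1 was also compared by exact two-sided permutation tests.

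For each comparison with calls, the genes named were taken from up to 15 called in each direction with the largest change, among features with an assigned gene name. For a comparison with fewer than 10 calls, they were also the 5 highest and the 5 lowest changes among features with an unadjusted p under 0.01 and a mean above the median feature, which had failed the adjusted threshold. Members of a described list that passed, or that had the smallest p, and Nlrx1 completed the rule. A few called members of other lists, as well as 1 feature without a gene symbol, were chosen after their values had been seen, and the text says so where they stand.

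Gene lists, 33 in all, covered pathways and the marker genes of cell types that a tumour in the fat pad could hold. Each was tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Counts are given over all features tested and adjusted over the list alone. The deviation of a list on an array was the median, over its genes, of the value minus the gene's median over the fitted arrays.

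The alternative settings were all 12 arrays, quantile normalization on top of the deposited values, leaving out the dimmest 33.3% of features, an intensity trend with robust hyperparameters, array weights, the console's usual threshold (unadjusted p under 0.05 and a fold of 2 or more), the replicate number as a block, 1 mean per group or the compared groups alone, and each array left out in turn. Alternatives added after seeing the data were the standard deviation of each array's values as a covariate, leaving out the arrays where it was under 3, and leaving out the 2 fitted arrays with high lymph node genes.

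Each comparison was tested on simulated data with log2 changes of 1, 2 and 4 placed in known features. For 4T1OE against 4T1OE-CTL tumours 34.3%, 80.6% and 98.5% of these were called, for the genotype averaged over the lines 56.7%, 95.5% and 100%, and for the interaction 0%, 5.97% and 78.8%. The simulated noise was independent between features and held no array-wide difference in spread. The changes were placed only in features with a mean above the median feature. These shares can therefore be too high for the real arrays, and a lack of calls does not show that such changes are absent. The number of arrays limits the precision.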

Results

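The series comprised 12 arrays of pooled tumour RNA, 2 for each combination of host genotype (WT or Nlrx1-/-) and injected cell line (parental 4T1, 4T1OE-CTL or 4T1OE). After 1 Nlrx1-/- parental array had been left out, 3 parental, 4 4T1OE-CTL and 4 4T1OE arrays remained, 6 from WT and 5 from Nlrx1-/- hosts. All expression values and differences are on the log2 scale. Where a gene lay under the negative control median of every array on 1 side of a comparison, its difference is given as at least a bound. The 4T1OE arrays had standard deviations of their values of 3.09 to 3.12, whereas those of 4T1OE-CTL arrays ran from 2.78 to 3.07 and those of parental arrays from 2.89 to 3.07. The value was under 3 on 3 of 4 4T1OE-CTL arrays, 1 of 3 parental arrays and 0 of 4 4T1OE arrays. Those of the 4T1OE-CTL line were both Nlrx1-/- arrays and WT replicate 1.

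The design sets a host without Nlrx1 against tumour cells overexpressing NLRX1, a mitochondrial member of the NOD-like receptor family. The species of the construct was not given in the sources used here, so how fully the mouse array's Nlrx1 feature measures it is not known. Its mean was 9.98 ± 0.555 (SD, n = 4) in 4T1OE tumours, 6.59 ± 0.497 (n = 4) in 4T1OE-CTL tumours and 6.62 ± 0.497 (n = 3) in parental tumours. Every 4T1OE array lay above every other array, with a difference in means of 3.37 between the 4 4T1OE arrays and the other 7 (exact two-sided permutation test, p = 0.00303, the smallest its 330 splits can give). In the limma fit Nlrx1 was 3.39 higher in 4T1OE than in 4T1OE-CTL tumours (SE 0.336, adjusted p = 0.00227). The call ended with the array standard deviation as a covariate (2.77, adjusted p = 0.0777) and without the arrays where it was under 3 (2.92, adjusted p = 0.126). Under the other settings the adjusted p was 0.00106 to 0.0201.

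Nlrx1-/- hosts did not differ detectably from WT hosts in Nlrx1. Among parental and 4T1OE-CTL tumours the mean was 6.33 ± 0.314 (SD, n = 3) in Nlrx1-/- and 6.81 ± 0.459 (n = 4) in WT hosts, a difference of -0.49 (exact two-sided permutation test, p = 0.171, with 0.0286 the smallest p possible). Among 4T1OE tumours the difference was 0.65 (exact two-sided permutation test, p = 0.667, with 2 arrays against 2 and 0.333 the smallest p possible). The injected cells carry their own Nlrx1 gene in either host, so these values do not check the host's genotype.

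**Figure D1:**
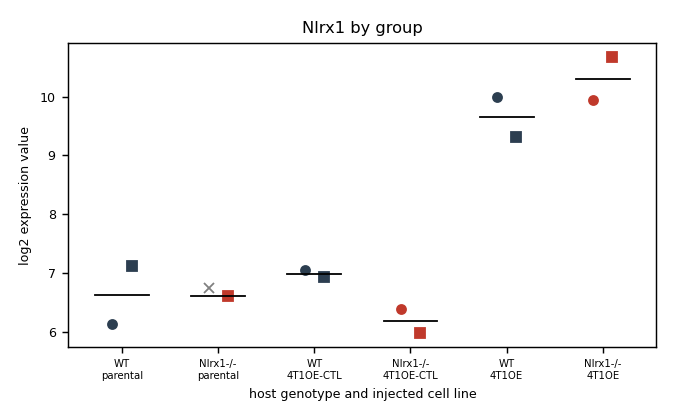
Nlrx1 expression value (log2, vertical axis) on each tumour array by host genotype and injected cell line (horizontal axis); circles are replicate 1, squares replicate 2, dark marks WT and red marks Nlrx1-/- hosts, the grey cross is the array left out of the fits, and lines are means of the fitted arrays. The 4 arrays of 4T1OE tumours average 9.98, against 6.59 for 4T1OE-CTL and 6.62 for parental tumours.

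The main comparison asked which genes differ between tumours of the overexpressing line and tumours of its transduced control. All arrays of each side came from the same transduced line. An effect of overexpression therefore cannot be told from any other difference between these lines. Tslp, an epithelial cytokine, fell by 3.12 (SE 0.251, adjusted p = 0.000401), from 13.0 ± 0.486 (SD, n = 4) in 4T1OE-CTL to 9.89 ± 0.286 (n = 4) in 4T1OE tumours. Mgst1, a microsomal glutathione transferase, fell by 2.75 (SE 0.216, adjusted p = 0.000401), from 13.3 ± 0.287 to 10.5 ± 0.303. Both genes were lower on all 4 4T1OE arrays than on any 4T1OE-CTL array. Parental tumours lay between, with means of 11.4 for Tslp and 12.3 for Mgst1 (n = 3). Tslp was 1.65 higher in 4T1OE-CTL than in parental tumours (limma, adjusted p = 0.00902). It was 1.47 lower in 4T1OE than in parental tumours (limma, adjusted p = 0.0264), so its fall was partly a rise in the control line. The complement genes C1s1, C1s2, C4a and C4b fell by 2.34, 2.22, 2.12 and 2.09, while C1qb, also of the complement system, rose by 1.98. Lower too were the Ly6 family genes Ly6c1 (-3.56) and Ly6e (-2.64), granzyme B (Gzmb, -2.55), the mast cell protease gene Mcpt1 (-2.75), Epb41l4a (-2.52), the coagulation factor gene F5 (-2.23), Plac8 (-2.18) and the interferon-inducible GTPase genes Tgtp2 (-2.37) and Igtp (-2.09).

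At the upper end of the same comparison, Fcrls, a gene of myeloid cells, rose by 4.47 (SE 0.533, adjusted p = 0.00424), from 7.41 ± 0.679 to 11.9 ± 0.875 (SD, n = 4 each). Cx3cr1, the fractalkine receptor, rose by 3.33, Folr2 by 3.14, the chemokine gene Ccl12 by 2.91 and Gpr34 by 2.84. The others named by the rule, besides Nlrx1, were Mest (3.71), Dmp1 (3.70), the kappa-casein gene Csn3 (3.36), the syndecan gene Sdc2 (3.25), Npl (3.02), Chn1 (2.98), Cbr2 (2.89), the Tie2 ligand gene Angpt1 (2.86) and Gas6 (2.73), whose product is a ligand of Axl and Mertk.

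Of 19 macrophage markers 6 rose and none fell, and 15 rose when adjusted over the list alone. Besides Folr2 these were Csf1r (2.32), the receptor for macrophage colony-stimulating factor, the mannose receptor gene Mrc1 (2.19), Cd163 (2.00), C1qb (1.98) and Mertk (1.10). The list's median difference was 1.22 (camera, adjusted p = 2.03e-08; adjusted p = 0.651 with an estimated correlation). On the arrays, the macrophage list deviated by 0.21 to 0.53 in 4T1OE tumours and by -1.90 to -0.02 in 4T1OE-CTL tumours, and the 3 4T1OE-CTL arrays with a standard deviation under 3 were its 3 lowest there. With that standard deviation as a covariate the median was 0.30, and without the arrays under 3 it was 0.36. The same list was lower in 4T1OE-CTL than in parental tumours, with a median of -0.49, 15 of 19 negative, 0 passing in limma and 2 lower adjusted over the list alone (camera, adjusted p = 0.00793; adjusted p = 0.565 with an estimated correlation). Endothelial markers had a median of 0.64, with Cdh5 (2.03), Flt1 (1.76), Plvap (1.48) and Ptprb (at least 0.73) risen, 4 of 20 (8 higher and 2 lower adjusted over the list alone; camera, adjusted p = 0.00186; adjusted p = 0.651 with an estimated correlation).

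Type I interferon response genes were lower in 4T1OE than in 4T1OE-CTL tumours. Of 28 measured genes 7 fell, 11 adjusted over the list alone, among them Herc6 (-1.70), Bst2 (-1.47), Xaf1 (-1.31) and Ifit1 (-0.99). The list's median was -0.86 (camera, adjusted p = 2.03e-08; adjusted p = 0.651 with an estimated correlation). Cytotoxic and NK cell markers had a median of -0.55, and Gzmb, Gzma (-1.51) and Fasl passed as lower, 3 of 18 (8 adjusted over the list alone; camera, adjusted p = 5.45e-05; adjusted p = 0.0553 with an estimated correlation). Fasl lay under the negative control medians in both lines, so no size is given for it. T cell markers moved with them, with a median of -0.54 and all 15 negative, 0 passing in limma in either count (camera, adjusted p = 0.0193; adjusted p = 0.692 with an estimated correlation). So did skeletal muscle markers, with a median of -0.65 and 21 of 22 negative, 1 fallen in both counts (camera, adjusted p = 0.0462; adjusted p = 0.769 with an estimated correlation). The muscle list differed widely between arrays of the same group, with values given further on. Of the antigen presentation and interferon gamma list, 2 of 27 genes fell, Gbp4 (-1.98) and Igtp, and Tapbp (1.16) rose, with 8 lower and 2 higher adjusted over the list alone (median -0.60; camera, adjusted p = 0.000464; adjusted p = 0.651 with an estimated correlation). Among 18 immune checkpoint genes Cd274, which encodes PD-L1, fell by 1.24 and Pdcd1lg2 by 1.79, and Ido1 passed as lower with values too near the negative controls for a size, the same 3 when adjusted over the list alone, but the list did not pass (median -0.29; camera, adjusted p = 0.0585). These 3 genes were chosen after their values had been seen. The 4T1OE-CTL arrays were themselves higher than parental arrays in these lists, as described further on. Both comparisons use the same 4 4T1OE-CTL arrays, so opposite signs in them are partly built in.

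Among the other lists, autophagy genes had a median of 0.45, with Atg9a (1.19) and Lamp1 (0.76) risen, 2 of 25 (4 higher and 1 lower adjusted over the list alone; camera, adjusted p = 0.00220; adjusted p = 0.651 with an estimated correlation). With the array standard deviation as a covariate the autophagy median was -0.11. Antioxidant genes also had a median of 0.45, with Gsta4 (1.72) and Cat (1.55) risen, 2 of 22 (4 higher and 1 lower adjusted over the list alone; camera, adjusted p = 0.00765; adjusted p = 0.651 with an estimated correlation). Of 51 oxidative phosphorylation genes 4 rose, in both counts (median 0.35; camera, adjusted p = 0.00186; adjusted p = 0.692 with an estimated correlation). Apoptosis and p53 target genes had a median of 0.35, with Cdkn1a (1.87) and Zmat3 (1.00) risen and Fasl passing as lower among 24 genes (7 higher and 1 lower adjusted over the list alone; camera, adjusted p = 0.0245; adjusted p = 0.655 with an estimated correlation). NF-kB target and cytokine genes did not pass as a list (median -0.29; camera, adjusted p = 0.678), with 2 of 31 risen and 1 fallen (2 and 2 adjusted over the list alone). The list of NLR, inflammasome and MAVS signalling genes did not pass (median 0.07; camera, adjusted p = 0.701), while Casp1 (-1.60) and Casp4 (-1.06) fell and Cgas (1.19) rose among its 24 genes, in both counts. These 3 were chosen after their values had been seen. Mast cell markers had a median of -0.51 with 0 of 12 passing in limma in either count (camera, adjusted p = 0.0462; adjusted p = 0.651 with an estimated correlation).

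Over all features, 1051 passed in this comparison, 820 higher and 231 lower in 4T1OE tumours (limma), and 5363 had an unadjusted p under 0.05. After quantile normalization 577 passed, 373 higher and 204 lower, so the share higher was 64.6% in place of 78.0%. The count was 4 (0 higher, 4 lower) with the array standard deviation as a covariate, 15 without the arrays where it was under 3, 25 with all 12 arrays and 60 without the 2 arrays with high lymph node genes, while Tslp and Mgst1 passed under each of these 4. All 1051 differences kept their sign under those settings, and the count ran from 70 without Nlrx1-/- 4T1OE replicate 1 to 2663 without WT 4T1OE-CTL replicate 2. The fit with 2663 left only 4T1OE-CTL arrays with a standard deviation under 3, against 4T1OE arrays all above it. Whether this raised the count was not tested.

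**Figure D2:**
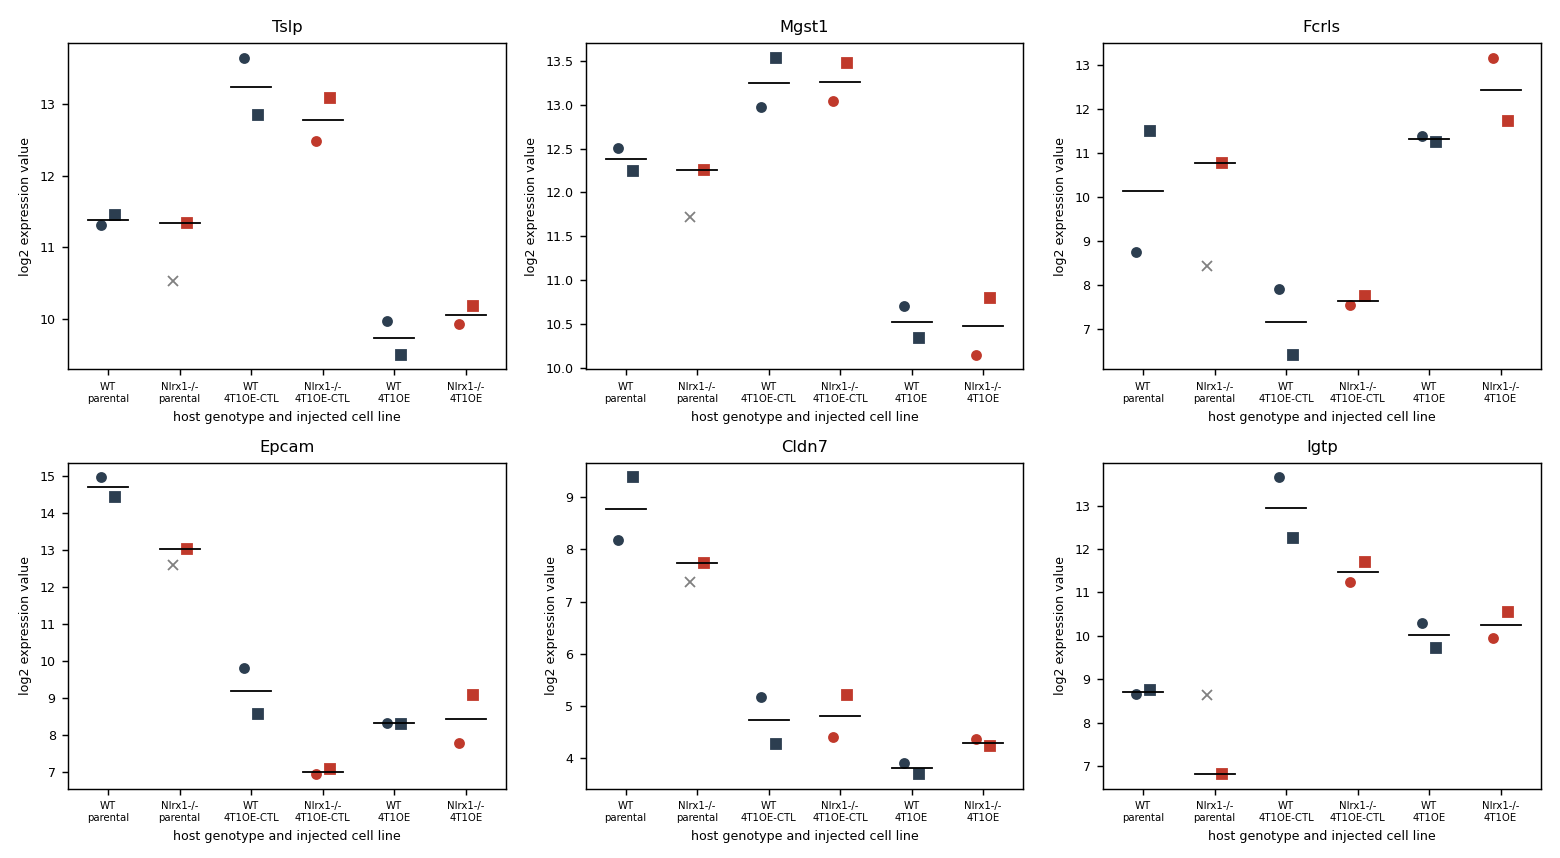
Expression values (log2, vertical axes) of 6 genes on each tumour array by host genotype and injected cell line (horizontal axes), with marks as in the plot of Nlrx1. Tslp and Mgst1 are lowest in 4T1OE tumours (means 9.89 and 10.5), Fcrls is lowest in 4T1OE-CTL tumours (7.41), Epcam and Cldn7 are highest in parental tumours (14.1 and 8.44) and Igtp is highest in 4T1OE-CTL tumours (12.2).

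Within each host, 4T1OE was compared with 4T1OE-CTL tumours on 2 arrays against 2, and the difference is called the overexpression effect below. In WT hosts Tslp fell by 3.51 (SE 0.348, adjusted p = 0.0196) and the phosphatase gene Ptpn13 by at least 2.27 (adjusted p = 0.0348). The third feature called, TC1500001728.mm.2, has no gene symbol in the annotation available and was named after its values had been seen, with -5.80 (SE 0.371, adjusted p = 0.000667). Among features with an unadjusted p under 0.01 and a mean above the median feature, the largest differences that failed the adjusted threshold were Mest (4.16), Fcrls (4.15), Fcna (at least 2.51), Gas6 (3.25) and Folr2 (3.13), and at the other end Ly6c1 (-4.08), Ly6c2 (-3.59), Igfbp5 (-3.34), Tgtp2 (-3.18) and Ly6e (-3.14). Nlrx1 itself was 2.66 higher (adjusted p = 0.0921). In all, 0 features passed as higher and 3 as lower in limma, with 1793 at an unadjusted p under 0.05, and with all 12 arrays none passed. The count was 31 (16 higher, 15 lower) with the compared groups alone and 26 (9 higher, 17 lower) with array weights. It was 1 with the replicate number as a block.

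In Nlrx1-/- hosts Nlrx1 rose by 4.11 (SE 0.407, adjusted p = 0.0141). Dmp1 rose by 4.93, Fcrls by 4.79, Chn1 by 3.93, Csn3 by 3.83, Sdc2 by 3.71, Npl by 3.42, Tpcn1 by 3.41, Npnt by 3.35, Mest by 3.26, Folr2 by 3.15 and the E-cadherin gene Cdh1 by 3.08. Mgst1 fell by 2.77, Tslp by 2.73, Plac8 by 2.63, C1s1 by 2.46, the integrin gene Itga8 by 2.15, C4b by 2.14 and the interferon-induced Herc6 by 1.71. In all, 265 features passed, 244 higher and 21 lower. After quantile normalization 45 and 12 did, so the share higher was 92.1% and 78.9%. Both 4T1OE-CTL arrays of these hosts had a standard deviation under 3 (2.914 and 2.776) and neither 4T1OE array did. The spread of values within arrays thus went with overexpression here. The count was 1 with all 12 arrays, with the compared groups alone and with the array standard deviation as a covariate. It was 0 without the 2 arrays with high lymph node genes and 57 with the replicate number as a block. With single arrays left out it was 0 without either Nlrx1-/- 4T1OE array or without Nlrx1-/- 4T1OE-CTL replicate 2, and 1341 without Nlrx1-/- 4T1OE-CTL replicate 1.

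Whether the overexpression effect differed between the hosts was tested as an interaction. No feature passed in limma, and 726 had an unadjusted p under 0.05. Among features with an unadjusted p under 0.01 and a mean above the median feature, the highest values were Krt7 (3.48, SE 0.792), a keratin gene, the protease genes Prss22 (2.98) and Tmprss11e (2.91), Npnt (2.98) and Macc1 (2.84), and the lowest were Defb45 (-1.66), Tppp (-1.52), Sh3bgr (-1.50) and Tubd1 (-1.24), all with an adjusted p of 0.999. The antigen presentation list had a median interaction of 1.13 with all 27 genes positive and none passing, 0 adjusted over the list alone (camera, adjusted p = 4.73e-13; adjusted p = 0.164 with an estimated correlation). Epithelial genes had one of 0.94, with 6 positive adjusted over the list alone (camera, adjusted p = 1.37e-06; adjusted p = 0.524 with an estimated correlation), and unfolded protein and integrated stress response genes one of 0.52, with 0 (camera, adjusted p = 0.00158; adjusted p = 0.599 with an estimated correlation). Skeletal muscle markers had one of -1.40, with 0 (camera, adjusted p = 0.00672; adjusted p = 0.763 with an estimated correlation). The muscle list differed widely within groups. It deviated by 3.44 and -0.654 on WT 4T1OE replicates 1 and 2, and by 0.00 and 2.42 on the Nlrx1-/- 4T1OE-CTL ones. Across features, which are not independent replicates, the overexpression effects in WT and in Nlrx1-/- hosts had a Pearson r of 0.640 and a Spearman rho of 0.588, and r was 0.390 without WT 4T1OE-CTL replicate 1.

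The transduced control line was next compared with the parental line. Epithelial genes were far lower in 4T1OE-CTL tumours. Epcam, an epithelial adhesion molecule, fell by 5.84 (SE 0.507, adjusted p = 0.000619), from 14.1 ± 0.998 (SD, n = 3) in parental to 8.09 ± 1.36 (n = 4) in 4T1OE-CTL tumours. The claudin genes Cldn4 and Cldn7 fell by 5.83 and by at least 2.94, and the splicing regulator gene Esrp1 by 3.26. Of 24 epithelial genes 11 fell, 17 adjusted over the list alone, including Cdh1 (-2.97), Grhl2 (-2.79), Jup (-2.63) and Dsp (-2.52), and the median was -1.65 (camera, adjusted p = 8.15e-16; adjusted p = 0.0427 with an estimated correlation). Other genes that fell were Mir675 (-3.69), the matrix proteoglycan gene Lum (-3.62), Perp (-3.55), the kinase gene Nuak1 (-3.52), Moxd1 (-3.49), the growth factor gene Pdgfc (-3.43), the interleukin 23 subunit gene Il23a (-3.29), Gadd45a (-3.10), Macc1 (-3.10), Mest (-3.09) and the transferrin gene Trf (-3.08).

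Interferon-responsive genes were higher in 4T1OE-CTL than in parental tumours. Cxcl9, a chemokine induced by interferon gamma, rose by 5.84 (SE 0.790, adjusted p = 0.00269), from a parental mean of 9.35 ± 2.48 (SD, n = 3). Its SD was 0.895 in 4T1OE-CTL tumours (n = 4). Of the antigen presentation and interferon gamma list 14 of 27 genes rose, 23 adjusted over the list alone, among them Gbp4 (4.59), Igtp (4.29), Iigp1 (4.27) and Gbp3 (2.95), with a median of 1.93 (camera, adjusted p = 4.05e-24; adjusted p = 0.0427 with an estimated correlation). Type I interferon genes had a median of 1.42, and 17 of 28 rose, 23 adjusted over the list alone, such as Ifit3 (2.74), Herc6 (2.55), Irf7 (2.22) and Ifit1 (1.96; camera, adjusted p = 1.95e-24; adjusted p = 0.0427 with an estimated correlation). The antigen presentation list deviated by -2.16 on the fitted Nlrx1-/- parental array and by -0.495 and -0.636 on the WT parental arrays. For the type I interferon list these values were -1.08, -0.325 and -0.582. Every 4T1OE-CTL array lay above every fitted parental array in both lists. Ly6c1 (5.27), Ly6c2 (4.61), Mcpt1 (at least 3.15), Ccl8 (4.07), Tgtp2 (4.02), Plac8 (3.97), the superoxide dismutase gene Sod3 (3.95), F5 (at least 3.55), Irgm2 (3.46) and C4b (3.23) rose as well.

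Cytotoxic and NK cell markers had a median of 0.87 in 4T1OE-CTL against parental tumours, and 5 of 18 rose (8 adjusted over the list alone), namely Gzmb (4.31), Gzma (3.01), Nkg7 (at least 1.07), Ifng (at least 0.81) and Klrk1 (1.69), a call kept with an estimated correlation (camera, adjusted p = 8.95e-09; adjusted p = 0.0104 with an estimated correlation). T cell markers moved with them, with a median of 0.86, 14 of 15 positive and 0 passing in limma in either count (camera, adjusted p = 0.000290; adjusted p = 0.565 with an estimated correlation). So did lymph node markers (median 0.71, 11 of 11 positive, 1 risen in both counts; camera, adjusted p = 0.0217; adjusted p = 0.565 with an estimated correlation) and neutrophil markers (median 0.51, 18 of 20 positive, 0 in either count; camera, adjusted p = 0.00856; adjusted p = 0.565 with an estimated correlation). The lymph node and T cell lists deviated by 3.03 and 1.93 on Nlrx1-/- 4T1OE-CTL replicate 1, and by at most 0.625 and 0.493 on the line's other arrays. The left-out parental array, at 2.85 and 1.24, is missing from the other side of this comparison. The neutrophil list ran from -0.887 on Nlrx1-/- 4T1OE-CTL replicate 1 to 1.30 on WT 4T1OE-CTL replicate 1. Immune checkpoint genes had a median of 0.70, and Cd274 (2.92) and Pdcd1lg2 (2.76) rose among 18 (4 adjusted over the list alone; camera, adjusted p = 7.71e-06; adjusted p = 0.0427 with an estimated correlation). Cell cycle genes had a median of 1.19, and 11 of 32 rose, 27 adjusted over the list alone, such as Rrm2 (2.36), Ube2c (1.95), Plk1 (1.93) and Mki67 (1.68; camera, adjusted p = 1.78e-21; adjusted p = 0.222 with an estimated correlation). The cell cycle list deviated by -2.15 on the fitted Nlrx1-/- parental array, and by -0.798 and -0.434 on the WT parental arrays. On the 4T1OE-CTL arrays it ran from -0.296 to 0.936. Fibroblast and pericyte markers had a median of -0.50, and Lum, Rgs5 (-2.14) and Acta2 (-1.82) fell, 3 of 19 (7 lower and 1 higher adjusted over the list alone; camera, adjusted p = 0.00137; adjusted p = 0.152 with an estimated correlation). Endothelial markers had a median of -0.56 with Cdh5 (-2.10) fallen, 1 of 20 in both counts (camera, adjusted p = 0.00139; adjusted p = 0.416 with an estimated correlation). Autophagy genes had a median of -0.50 with Ulk2 (-1.50) fallen, 1 of 25 (8 adjusted over the list alone; camera, adjusted p = 6.57e-05; adjusted p = 0.416 with an estimated correlation). NF-kB target and cytokine genes had a median of 0.87 with Ccl4 (1.39) risen, 1 of 31 (8 adjusted over the list alone; camera, adjusted p = 7.53e-08; adjusted p = 0.333 with an estimated correlation).

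Skeletal muscle markers moved with this comparison, with a median of 1.76 and 1 of 22 genes risen, in both counts (camera, adjusted p = 3.65e-08; adjusted p = 0.504 with an estimated correlation). On the arrays the muscle list deviated by 3.44 in WT 4T1OE replicate 1, by 2.42 in Nlrx1-/- 4T1OE-CTL replicate 2, by 2.12 in WT 4T1OE-CTL replicate 1 and by 0.85 in WT 4T1OE-CTL replicate 2, and by 0.0109 or less on the other fitted arrays. Over all features 575 passed, 215 higher and 360 lower in 4T1OE-CTL tumours (limma), with 3532 at an unadjusted p under 0.05. The count was 157 (111 higher, 46 lower) with all 12 arrays and 142 without the arrays with a standard deviation under 3. It was 126 without the fitted Nlrx1-/- parental array, 293 without WT parental replicate 2 and 880 without WT parental replicate 1.

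A comparison of 4T1OE with parental tumours was added after the data had been seen, since the control line had differed so widely from the parental line. Cldn4 fell by 6.78 (SE 0.856, adjusted p = 0.00573), from 14.5 ± 0.750 (SD, n = 3) to 7.55 ± 0.814 (n = 4), Epcam by 5.56 and Cldn7 by at least 3.11. Of the epithelial list 9 of 24 genes fell (13 adjusted over the list alone; median -1.23; camera, adjusted p = 4.10e-14; adjusted p = 0.191 with an estimated correlation). Cell cycle genes had a median of 1.47, and 12 of 32 rose (28 adjusted over the list alone), such as Ube2c (2.68), Ccna2 (2.46) and Mki67 (2.32; camera, adjusted p = 2.21e-30; adjusted p = 0.191 with an estimated correlation). Here too the fitted Nlrx1-/- parental array was the lowest for the cell cycle list (-2.15). Of the antigen presentation list 8 of 27 rose (13 adjusted over the list alone), such as Cxcl9 (4.43), Cxcl10 (3.02) and Iigp1 (2.71), with a median of 1.21 (camera, adjusted p = 2.52e-15; adjusted p = 0.191 with an estimated correlation). Type I interferon genes had a median of 0.71, with 0 of 28 passing in limma and 5 adjusted over the list alone (camera, adjusted p = 6.00e-09; adjusted p = 0.221 with an estimated correlation). The same parental array was also the lowest fitted array for the antigen presentation list (-2.16) and the type I interferon list (-1.08). Fibroblast markers had a median of -0.40, and 5 of 19 fell, 7 adjusted over the list alone, including Lum (-2.65), Col1a2 (-2.35) and Col1a1 (-2.23; camera, adjusted p = 9.61e-05; adjusted p = 0.191 with an estimated correlation). Outside these lists Sod3 (4.83), Pmp22 (3.67), the P-selectin gene Selp (at least 2.08), Nlrx1 (3.37), Dnase1l3 (at least 1.87), Steap1 (3.00) and the drug efflux transporter gene Abcb1b (2.70) rose. Genes that fell were Epb41l4a (-3.45), Tnnt2 (-3.25), the periostin gene Postn (-3.10), Esrp1 (-2.96), Nuak1 (-2.83), Prom2 (-2.81), Rab25 (-2.55), Hunk (-2.52) and Cldn3 (-2.50).

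Of the 22206 features 295 passed in that comparison, 197 higher and 98 lower in 4T1OE tumours, and after quantile normalization 116 and 121, so the share higher was 66.8% and 48.9%. The count was 151 (75 higher, 76 lower) with the array standard deviation as a covariate and 98 without the arrays with high lymph node genes, and from 83 to 342 with single arrays left out, the lowest without the fitted Nlrx1-/- parental array. Of the features called, 63 were higher and 58 lower than in parental tumours in both transduced lines. Independent lists would share 1.91 and 1.59. Tslp alone was called in opposite directions. Both comparisons use the same 3 parental arrays. In 100 simulations with those arrays shared and no real difference, the differences of all features correlated by 0.579 on average, against 0.461 observed, and 69.7% had the same sign, against 58.2%. These 2 measures cannot decide whether the lines share a difference from parental tumours, since a difference particular to 1 line lowers both. The covariance of the 2 comparisons was 0.131, against 0.0672 in the simulations. The simulations called 0.01 features on average in both in the same direction, which says little, as they call almost none in either.

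The last question was what the host's own Nlrx1 changes. Averaged over the 3 lines, no gene passed between Nlrx1-/- and WT hosts (limma, 6 WT and 5 Nlrx1-/- arrays), with 955 features, or 4.30%, at an unadjusted p under 0.05. Among features with an unadjusted p under 0.01 and a mean above the median feature, the largest differences were lower values in Nlrx1-/- hosts of the collagenase gene Mmp13 (-2.12, SE 0.639), Cdh1 (-2.03, SE 0.426), the gelatinase gene Mmp9 (-1.81, SE 0.368), Tmprss11e (-1.59) and the metallothionein gene Mt2 (-1.59). Values were higher for Satb1 (1.87, SE 0.567), B3gnt5 (1.37), the selenoprotein gene Selenop (1.16), Slc6a2 (1.05) and F13a1 (1.03), each with an adjusted p of 1.00. Without WT 4T1OE-CTL replicate 2, Mmp9 alone passed (-2.23).

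Among the lists, cell cycle genes had a median of -0.70 between Nlrx1-/- and WT hosts, with 0 of 32 passing in limma and 11 lower adjusted over the list alone, such as Prc1 (-1.26), Kif20a (-1.11) and Bub1 (-1.10; camera, adjusted p = 4.08e-22; adjusted p = 0.312 with an estimated correlation). By line the cell cycle median was -1.62 in parental tumours, where 1 array stands for the Nlrx1-/- hosts, -0.77 in 4T1OE-CTL and -0.06 in 4T1OE tumours. Antigen presentation genes had a median of -0.51, with Iigp1 at -1.32, Gbp2 at -1.22 and Gbp3 at -1.17, and 0 of 27 passing in either count (camera, adjusted p = 1.19e-10; adjusted p = 0.312 with an estimated correlation). By line, in the same order, it was -1.50, -0.82 and 0.12. Epithelial genes had a median of -0.36 with 0 of 24 passing and 4 lower adjusted over the list alone (camera, adjusted p = 2.33e-08; adjusted p = 0.312 with an estimated correlation), and by line -0.67, -0.85 and 0.12. B and plasma cell markers had a median of 1.39 and lymph node markers one of 1.17, with 0 of 15 and 0 of 11 passing in either count (camera, adjusted p = 3.19e-09 and 9.56e-06; for both adjusted p = 0.312 with an estimated correlation). T cell markers had a median of 0.62, skeletal muscle markers one of -0.67, neutrophil markers one of -0.39 and immediate early and heat shock genes one of -0.43, with 0 passing in limma in either count (camera, adjusted p = 3.23e-05, 0.000101, 9.87e-05 and 1.84e-05; in the same order adjusted p = 0.424, 0.534, 0.424 and 0.312 with an estimated correlation). The B cell and lymph node lists were high on replicate 1 of the Nlrx1-/- 4T1OE and 4T1OE-CTL arrays, where the lymph node list deviated by 2.89 and 3.03, against 0.63 or less on the other fitted arrays. The T cell list deviated by 1.41 and 1.93 there, against 0.493 or less on the others. The muscle list was highest on single arrays of both hosts, with 3.44 on WT 4T1OE replicate 1 and 2.42 on Nlrx1-/- 4T1OE-CTL replicate 2. The neutrophil list ran from -0.887 on Nlrx1-/- 4T1OE-CTL replicate 1 to 1.30 on WT 4T1OE-CTL replicate 1.

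Within single lines, no feature passed between the hosts either in limma, and the genes named next are extremes only among features with an unadjusted p under 0.01 and a mean above the median feature. Among parental tumours 1044 had an unadjusted p under 0.05, and the fitted Nlrx1-/- array differed from the 2 WT arrays most in the granzyme genes Gzmg (5.15, SE 1.26), Gzmf (4.54) and Gzmc (3.51) and the angiopoietin gene Angpt2 (2.98) at the upper end. At the lower end were Cxcl9 (-4.25, SE 0.615), Ly6c1 (-4.03), Tgtp2 (-3.28) and the class II genes H2-Aa (-3.19) and H2-Eb1 (-3.10). Among 4T1OE-CTL tumours 2121 had an unadjusted p under 0.05, and the smallest adjusted p was 0.125. The extremes were Igfbp5 (-4.29, SE 0.976), Prss22 (-3.59), Tmprss11e (-3.38), Cdh1 (-3.36) and Krt7 (-3.36) against Ifi209 (2.82) and Cmah (2.80). Among 4T1OE tumours 194 had an unadjusted p under 0.05, with Mmp9 (-2.24), Mt2 (-1.97) and the iron exporter gene Slc40a1 (-1.88) lowest and Ubtd1 (1.08) highest. Across features, the genotype differences in 4T1OE-CTL and in 4T1OE tumours had a Pearson r of 0.228 and a Spearman rho of 0.0881, and r was -0.0522 without Nlrx1-/- 4T1OE-CTL replicate 1.

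**Figure D3:**
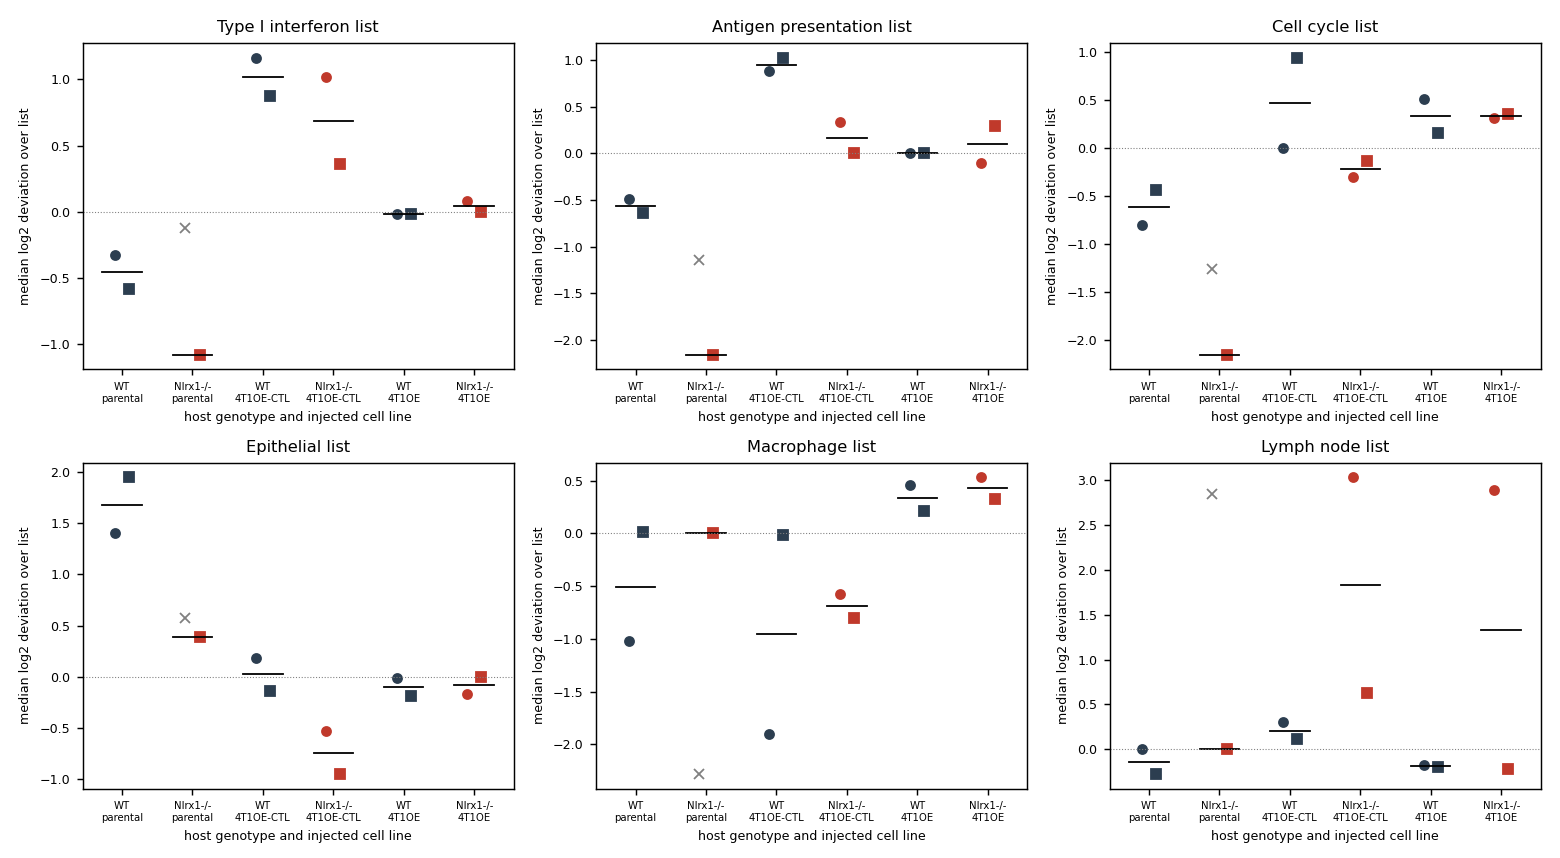
Deviation of 6 gene lists on each tumour array (vertical axes, median over the list's genes of the log2 value minus the gene's median over the fitted arrays) by host genotype and injected cell line (horizontal axes), with marks as in the plot of Nlrx1. The macrophage list lies between 0.21 and 0.53 on the 4 4T1OE arrays, and the lymph node list between 2.85 and 3.03 on the 3 Nlrx1-/- replicate 1 arrays.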

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

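The tests of the lymph node genes, of the spread of values within arrays and of the epithelial genes were chosen after the results they concern had been seen, as was the look at the left-out array, while the interaction and the tests of its lists had been fixed in advance.

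In 3 lists the overexpression effect differed between the hosts at an unadjusted p under 0.05, in a test of the difference itself. Antigen presentation and interferon gamma genes had a median difference of 1.13, with -1.31 in WT and -0.18 in Nlrx1-/- hosts (fry, unadjusted p = 0.00568). Epithelial genes had one of 0.941, with -0.03 in WT and 0.69 in Nlrx1-/- hosts (fry, unadjusted p = 0.0333). Genes of the unfolded protein and integrated stress response had one of 0.515, with 0.09 in WT and 0.57 in Nlrx1-/- hosts (fry, unadjusted p = 0.0448). All 3 passed with camera at the preset correlation (adjusted p = 4.73e-13, 1.37e-06 and 0.00158), and none passed after adjustment over the lists with fry (adjusted p = 0.187, 0.493 and 0.493) or with camera at an estimated correlation (adjusted p = 0.164, 0.524 and 0.599), and the groups held 2 arrays each. The array standard deviations were 2.914 and 2.776 for Nlrx1-/- 4T1OE-CTL tumours and 2.885 and 3.073 for WT ones. These ranges overlapped, as the WT array at 2.885 lay between the Nlrx1-/- ones. Whether the spread of values within arrays played a part in the difference between the hosts was not tested.

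The Nlrx1-/- parental replicate 1 array, which the fits did not use, held genes of lymph node structure far above their level on the WT arrays: Glycam1 13.2, Cxcl13 12.8, Ccl21a 12.1 and Cr2 7.84. The same genes were high on replicate 1 of the other 2 Nlrx1-/- groups, and the lymph node list deviated by 2.85 to 3.03 on these 3 arrays, against -0.27 to 0.63 on the other 9. A rise of this size from the host genotype, shared by its pools, is argued against. The 3 Nlrx1-/- replicate 2 arrays deviated by -0.224 to 0.625, against -0.274 to 0.299 on the 6 WT arrays. They lay below the 3 replicate 1 arrays by more than the spread of all other arrays. Their mean was 0.172 above that of the WT arrays, so a smaller rise stays open. Lymph node tissue in those pools stays open, as the mammary fat pad holds a lymph node: 6 of the list's 11 genes lay above all other arrays on the 3, but these include the 4 that drew attention to them, and the median deviation of the other 7 was not above every other array (lowest of the 3 minus highest other -0.259). B and plasma cell markers were higher on the 3 arrays too (13 of 15 above all other arrays), 3 of the 11 genes are also in another list, and organised lymphoid tissue within the tumours stays open.

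The 820 genes higher and 231 lower in 4T1OE than in 4T1OE-CTL tumours went with a difference in the spread of values within arrays. Tslp and Mgst1, the 2 with the smallest adjusted p, were looked at apart. With the array standard deviation as a covariate they were -2.96 (SE 0.363, before -3.12 and 0.251) and -2.69 (SE 0.312, before -2.75 and 0.216). The median ratio was 0.963 (0.871 without WT 4T1OE-CTL replicate 2 to 0.996). Both passed, as they did in 3 of the 11 refits that also left out 1 array. Picking the smallest adjusted p from the same fit favours genes that vary little within a line, and so a ratio near 1. The covariate therefore cannot decide whether this spread was their cause. For the higher genes the median went from 1.25 (median SE 0.264) to 0.75 (0.312), a median ratio of 0.604 (0.549 without WT 4T1OE-CTL replicate 2 to 0.675), and for the other 229 lower genes from -1.15 (0.247) to -0.75 (0.314), a median ratio of 0.693 (0.683 to 0.780). Of the higher genes 0 passed with the covariate in limma and 459 had an unadjusted p under 0.05, and of the other lower genes 2 and 145, since the differences shrank and their errors grew. A technical difference between arrays and an effect of overexpression cannot be told apart for these 820 and 229 genes as sets, because 3 of the 4 arrays with a standard deviation under 3 belong to the 4T1OE-CTL line. With 1 transduced line of each kind, another difference between the lines stays open too, also for Tslp and Mgst1, and was not tested.

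Epithelial genes were lower in both transduced lines than in parental tumours, by a median over the 24 genes of -1.65 in 4T1OE-CTL and -1.23 in 4T1OE tumours (camera with an estimated correlation, adjusted p = 0.0427 and 0.191, so the second call was lost). In 4T1OE tumours a lower share of cancer cells as the whole cause is argued against, since the list's other 22 genes changed on average by -1.60 relative to the abundant keratins Krt8 and Krt18 (95% interval -2.32 to -0.87). In 4T1OE-CTL tumours it stays open, since the same value was -0.703 with an interval that includes 0 (-1.43 to 0.02). For the called genes the covariate left median ratios of 0.978 and 0.973, with 9 of 11 and 7 of 9 still called. This argues against the spread of values within arrays as their whole cause in both comparisons. These genes were picked by their calls in the same fits, though, which favours ratios near 1. A difference between the cell lines themselves stays open and was not tested, with 1 transduced line of each kind.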

How the results depend on the processing

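The array standard deviation as a covariate, the fits without the 4 arrays where it was under 3 or without the 2 with high lymph node genes, and the comparison of 4T1OE with parental tumours were chosen after the data had been seen. All other settings were fixed before the data were examined. For each change below the cause was not tested, unless fewer arrays or features explain it.

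Among the genes named, none changed direction under any setting. Without the arrays under 3, 201 stayed on their side of the threshold, 119 lost and 8 gained their call, with 12 arrays 249 stayed and 139 lost it, with the covariate 262, 123 and 1, without the lymph node arrays 265, 118 and 5, with the compared groups alone 49, 30 and 9, after quantile normalization 331, 54 and 3, with the replicate number as a block 349, 37 and 0, and with the dimmest features left out 371 stayed and 5 gained it.

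The number of lists passing went from 17 for the genotype to 0 with an estimated correlation, 0 with fry and 7 without the lymph node arrays. It went for 4T1OE against 4T1OE-CTL from 16 to 0, 2 with fry, 7 after quantile normalization, and 10 both with the covariate and without the arrays under 3. It went for 4T1OE-CTL against parental from 17 to 5 and 7 with fry, for the interaction from 10 to 0, 0 with fry and 4 after quantile normalization, and for 4T1OE against parental from 19 to 0, 4 with fry and 12 with the covariate. Autophagy in 4T1OE against 4T1OE-CTL tumours reversed with the covariate (-0.111).

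The console threshold, which makes no adjustment, gave 102 genes for the genotype, 697, 908 and 47 for it in parental, 4T1OE-CTL and 4T1OE tumours, 1219 for 4T1OE-CTL against parental, 861 and 2667 for overexpression in WT and Nlrx1-/- hosts, 571 for the interaction and 1048 for 4T1OE against parental.

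With all 12 arrays the counts were 25 for 4T1OE against 4T1OE-CTL, 157 for 4T1OE-CTL against parental, and 0 and 1 for overexpression in WT and Nlrx1-/- hosts. Quantile normalization gave 577 for 4T1OE against 4T1OE-CTL and 57 for overexpression in Nlrx1-/- hosts. Array weights gave 2140 for 4T1OE against 4T1OE-CTL, 26 for overexpression in WT hosts and 666 for 4T1OE against parental. Leaving out the dimmest features gave 419 for overexpression in Nlrx1-/- hosts, and the compared groups alone gave 31 in WT and 1 in Nlrx1-/- hosts.

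With the covariate the counts were 4 for 4T1OE against 4T1OE-CTL, 1 for overexpression in Nlrx1-/- hosts and 151 for 4T1OE against parental, and Nlrx1 was 2.77, no longer called. Without the arrays under 3 they were 15 for 4T1OE against 4T1OE-CTL and 142 for 4T1OE-CTL against parental, and Nlrx1 was 2.92, no longer called. Without the lymph node arrays they were 60 for 4T1OE against 4T1OE-CTL, 1 and 0 for overexpression in WT and Nlrx1-/- hosts, and 98 for 4T1OE against parental.

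The replicate numbers did not pair the arrays throughout: deviations of the same number correlated by -0.31 to 0.37 over 10 pairs of groups, over 0.1 in 2. The highest was that of the Nlrx1-/- 4T1OE and 4T1OE-CTL groups, whose replicate 1 arrays share high lymph node genes, so pairing there stays open. With the replicate number as a block the counts were 882 for 4T1OE against 4T1OE-CTL, 480 for 4T1OE-CTL against parental, 295 for 4T1OE against parental, 1 and 57 for overexpression in WT and Nlrx1-/- hosts, and 0 in limma for the rest.

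With single arrays left out, the genotype count was 0 to 1 (1 without WT 4T1OE-CTL replicate 2), and that in 4T1OE-CTL tumours 0 to 1 (1 without WT parental replicate 1 or 2). For 4T1OE against 4T1OE-CTL it was 70 to 2663: 1831 without WT parental replicate 1, 320 and 87 without WT 4T1OE replicates 1 and 2, 70 and 207 without the Nlrx1-/- ones, 225 and 2663 without WT 4T1OE-CTL replicates 1 and 2, and 604 and 248 without the Nlrx1-/- ones. The 1831 came without the only fitted parental array with a standard deviation under 3. The 2663 came without the only 4T1OE-CTL array with one above 3. For 4T1OE-CTL against parental it was 126 to 880: 880 and 293 without WT parental replicates 1 and 2, and 126 without the fitted Nlrx1-/- parental array. For overexpression in WT hosts it was 1 to 12: 1 without any 4T1OE array or without WT 4T1OE-CTL replicate 1, and 12 without either Nlrx1-/- 4T1OE-CTL array. For overexpression in Nlrx1-/- hosts it was 0 to 1341: 667 without either WT parental array, 15 without either WT 4T1OE array, 0 without either Nlrx1-/- 4T1OE array or Nlrx1-/- 4T1OE-CTL replicate 2, and 1341 without replicate 1 of the latter. For 4T1OE against parental it was 83 to 342: 141 without WT parental replicate 1, 83 without the fitted Nlrx1-/- parental array, 90 and 104 without WT 4T1OE replicates 1 and 2, and 84 and 121 without the Nlrx1-/- ones.

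Lists passing ranged likewise from 13 to 18 for the genotype, 10 (without Nlrx1-/- 4T1OE-CTL replicate 1) to 17 for 4T1OE against 4T1OE-CTL, 15 to 19 for 4T1OE-CTL against parental, 8 to 16 (without Nlrx1-/- 4T1OE-CTL replicate 2) for the interaction and 16 to 20 for 4T1OE against parental. Nlrx1 was 3.11 to 3.65. The correlation of the genotype differences in the transduced lines was -0.0522 (without Nlrx1-/- 4T1OE-CTL replicate 1, reversed) to 0.413, and that of the overexpression effects 0.390 (without WT 4T1OE-CTL replicate 1) to 0.659.

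Without the arrays under 3 there is no value for the genotype in 4T1OE-CTL tumours, overexpression in Nlrx1-/- hosts or the interaction, nor for the genotype in parental tumours without its lone Nlrx1-/- array. Where 1 array remained in a group, it was assumed to vary as the others did.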

Other observations

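The tests by splits were set down before the counts of the other splits had been seen, though not before the real counts, and the comparison of 4T1OE with parental tumours was itself added after the data had been seen.

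The arrays were also split into other groups of the same sizes, in all possible ways for the cell lines and in 100 random ways for the genotype. For 4T1OE against 4T1OE-CTL tumours 1 of the 35 splits, the real one, gave as many genes (1051, highest other 0). This does not exclude chance, as every other split mixed the lines, which puts any line difference into the spread and lowers the count. For 4T1OE against parental tumours 1 of 35 did too (295, highest other 0), with the same limit. For 4T1OE-CTL against parental tumours chance cannot be excluded, as 2 of 35 splits gave as many (575, highest other 666). That other split put the 4 arrays with a standard deviation under 3 in 1 group, and with the array standard deviation as a covariate the real comparison gave 583. For the genotype, with 0 genes in limma (955 at an unadjusted p under 0.05), the splits say nothing on chance, as all 100 must give as many. The highest other, 124, grouped the 4 4T1OE arrays with Nlrx1-/- 4T1OE-CTL replicate 2. With cell line in the model, it sets that 1 array against the other 3 4T1OE-CTL arrays, and its cause was not tested.

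The hybridisation control cre had values of 13.1 to 13.6 on the 4 fitted arrays with a standard deviation under 3 and of 12.3 to 12.8 on the other 7. The first principal component of the fitted arrays held 33.6% of the variance and correlated with the array standard deviation by 0.984. What set this spread was not tested. The feature TC1500001728.mm.2, without a gene symbol, had values of 14.3 or more on the 4 4T1OE-CTL arrays (17.5 and 16.8 in WT hosts) and of 11.1 to 11.7 on the 4 4T1OE arrays.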
